A study of Mus musculus with 283 samples.

How the data were processed

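Total RNA from tumours, tumour-draining lymph nodes and spleens of mice carrying syngeneic tumours, from nodes and spleens of mice without tumours, and from the cultured tumour cell lines was amplified, labelled with biotin and hybridised to Affymetrix mouse exon arrays. The authors deposited 1 table of 283 arrays and 17831 probe sets whose values are on the log2 scale, made with the robust multi-array average method (RMA) according to the submitters' processing notes. RMA corrects the background, equalises the distribution of probe intensities between arrays and summarises the probes of each probe set. Its version, the set of arrays normalised together and the genome build are not given in the sources used here. The values ran from 0.4 to 12.93, and the medians of the arrays from 5.19 to 5.66, the range left after the authors' normalisation. No pair of arrays was identical (0 pairs), and the highest Pearson correlation between any pair was 0.984. RMA compresses changes of weakly expressed genes, and equalising distributions can hide a change that affects most genes.

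Probe sets were assigned to genes with the platform's annotation. Of the probe sets, 15620 named 1 gene symbol and were used, 1370 named several and 841 named none, and these were not used. Symbols were matched to RefSeq by gene identifier (15559 matched, 0 needed a new symbol). Where a gene had several probe sets (375 genes), the one with the highest mean over all arrays was kept, which left 15224 genes. Gene positions are those of the GRCm38.p6 assembly. A gene was tested in a comparison if its value was above 4.3, the 25th percentile of all values, in at least 4 of the arrays compared. The arrays' labelled sex was checked with the Y-linked genes Kdm5d and Eif2s3y. Kdm5d lay between 2.74 and 3.92 on the 241 arrays labelled female and between 6.21 and 7.60 on the 42 labelled male, and Eif2s3y between 1.40 and 3.25 and between 7.46 and 8.97.

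Groups, comparisons, gene lists, thresholds and alternatives were fixed before the data were examined, except where an alternative or test is said to have been chosen later. All models were fitted with limma 3.58.1 (lmFit and eBayes) in R 4.3.3. Tables and figures were prepared in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over the genes tested together with an absolute log2 fold change of at least 1. All tests were two-sided. The errors given as ± are standard errors of the fitted log2 fold change unless SD is written.

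Tumours were compared with cultures by subtracting each line's single culture array from the mean of its tumours. The 14 lines with both were reduced to 10 families, with the 4 B16 stocks averaged into 1 family and the 2 TRAMP-C lines into another, and the family differences were tested against 0. Each line had 1 culture array, so the family was the replicate. Tumours were compared among the 15 models by an F test with a range of group means of at least 1, and 5 pairs of related tumour groups by contrasts from the same fit to all 77 tumours. Each family was also set against the mean of the other families for the gene lists. Nodes and spleens of tumour-bearing mice were compared with organs of mice without tumours of the same strain and sex, in 1 fit per organ. The overall effect was the mean over families of tumour-bearing animals minus their own controls, over 10 families for nodes and 11 for spleens. Its error covers the spread between mice and not between models. Comparisons against the same controls share the chance values of those controls, so effects in models with common controls were not counted as independent repeats. Only 4 sets of controls exist, and the direction of a gene in each of the 4 is given instead. The difference of the effects in the 2 organs was fitted on nodes and spleens together. Animals gave both organs, so the fit was repeated with the animal as a replicate block.

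Named genes were taken by rule. For tumour against culture, the overall node and spleen effects and the difference between organs these were the 10 called genes with the highest and the 10 with the lowest log2 fold change, for pairs of tumours the 5 highest and 5 lowest, and for single models in an organ the 3 highest and 3 lowest. For tumours among models they were the 2 called genes per family with the highest family mean minus the mean of the other families. Members of gene lists and the sex check genes were also eligible. Predicted, antigen receptor segment and small RNA genes were counted but not named. Of 329 genes on 34 lists, 278 were matched to a measured gene. For 1 of them, H2-K1 on the MHC class I list, the match was wrong: an old synonym led to H2-Q10, a different gene. H2-K1 itself is only on probe sets that name several genes and was not measured, nor were H2-D1 and Nlrc5 of that list. The list was kept with H2-Q10 and tested again without it. The lists cover immune, blood and stromal cell types, neighbouring tissues, antigen presentation, interferon responses, cell cycle, metabolism and stress. Lists were tested with camera, which asks whether the genes of a list shift relative to all other genes, at a preset correlation of 0.01 between genes and again with a correlation estimated per list. List p-values were adjusted over the lists and comparisons of a family of comparisons. List counts are also given adjusted over the list alone.

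Alternatives fixed with the design were no filter on low values, a filter at 5.332 (the 50th percentile), no fold change minimum, array medians subtracted, quantile normalisation of the gene values again, the mean of a gene's probe sets, limma's trended and robust variance, the 14 lines each as a replicate, a fit to the compared groups only, equal weight per model, single strains, families as replicates, the animal as a replicate block, an estimated correlation in the list tests, and each array (for tumour against culture each family) left out in turn. Alternatives added after seeing the data left out nodes with few B cell transcripts, spleens and tumours rich in transcripts of neighbouring tissue, or either run of MC38 animal numbers, used the male controls of the strain, or took the adipocyte list mean as a covariate, and the list tests were repeated after quantile normalisation, without H2-Q10 and, in nodes of each model, without the 8 nodes with few B cell transcripts. Chance was tested by drawing 100 splits of the same samples, the real one included. The models were tested on simulated data with known changes, drawn with the means and spreads of the real genes. At a planted log2 change of 1.5, 62 of 67 genes (92.5%) were recovered in the node comparison of a single model and 67 of 67 in the overall node comparison. A planted erythroid shift of 1 was recovered (adjusted p = 1.48e-35), with 0 other lists called, but on uncorrelated genes.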

Results

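Gene expression was measured in mice carrying transplanted tumours of their own strain, models that are used to choose hosts for immunotherapy experiments because the immune system is intact. The arrays comprised 77 tumours from 15 models, 92 lymph nodes, 98 spleens and 16 cultured cell lines. Hosts were BALB/c females for 4T1 (mammary carcinoma), CT26 (colon carcinoma) and Renca (kidney carcinoma), DBA/2J females for P815 (mastocytoma), and C57BL/6J males for the prostate lines TRAMPC1 and TRAMPC2. C57BL/6J females carried the melanoma B16F0 from the suppliers ATCC and ECACC and its subline B16F10 from ATCC and NCI, LL2 (Lewis lung carcinoma), MC38 (colon carcinoma), EL4 (T cell lymphoma), TC1 (transformed lung epithelial cells) and PAN02 (pancreatic carcinoma). Tumours grew under the skin of the back, except PAN02, which grew in the pancreas and has no node group. Groups held 5 arrays, except MC38 with 8 tumours, 8 spleens and 7 nodes and PAN02 with 4 tumours. Mice without tumours gave 5 nodes and 5 spleens for each of 4 kinds of host. Each line was cultured once, with no replicate, and the lines Hepa1-6 and ID8 have no tumour arrays while TC1 has no culture array. Cultures and mice without tumours carry later sample numbers than tumour-bearing mice, so processing order cannot be told apart from culture or tumour bearing.

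The first comparison asked how tumours in the animal differ from the same lines in culture. Genes of macrophages, antigen presentation and connective tissue were higher in tumours. Genes of the cell cycle, amino acid supply and sterol synthesis were lower. As lists, 0 of the 27 that passed in this comparison did so with an estimated correlation between genes, and sterol synthesis did not pass after quantile normalisation either. Ctss, the lysosomal protease cathepsin S of antigen-presenting cells (gene identifier 13040, chromosome 3, 95526786 to 95556405), had the largest rise, with a log2 fold change of 4.70 ± 0.35 (n = 10 families, adjusted p = 3.12e-07), from a mean of 4.73 in cultures to 9.43 in tumours. Next came the monocyte chemokine receptor Ccr2 (4.42 ± 0.31), the myeloid adaptor Tyrobp (4.18 ± 0.36), the scavenger receptor Msr1 (4.08 ± 0.38), the myeloid membrane gene Ms4a6c (4.07 ± 0.34), the matrix proteoglycan decorin, Dcn (4.05 ± 0.49), and the monocyte chemokine Ccl12 (4.03 ± 0.41). Ms4a6d (3.64), the phagocyte oxidase subunit Cybb (3.64) and Cd52 (3.62) completed the 10 largest rises. The largest fall was in the cystine transporter Slc7a11 (identifier 26570, chromosome 3, 50364936 to 50499087), at -2.45 ± 0.24 (adjusted p = 1.84e-06), from 7.55 in cultures to 5.11 in tumours. The mitotic regulator Cdc20 followed at -2.29 ± 0.18 and the serine synthesis enzyme Psat1 at -2.12 ± 0.23. Falls between -2.06 and -1.98 were found for the desaturase Scd2, Cox19, the mitotic kinase Cdk1, Adh7, Gins1, Rnaseh2c and Rpp14. Every one of these 20 genes moved in the same direction in 10 of 10 families except Adh7, which fell in 8 of 10.

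The median log2 fold change over all genes in this comparison was -0.26, which quantile normalisation of the gene values brought to -0.02, and the list shifts that follow are relative to that median. The macrophage and monocyte list rose by 2.85 with 10 of 11 members called (10 adjusted over the list alone, adjusted p = 1.93e-15), among them the F4/80 antigen Adgre1 (2.53 before subtraction) and the mannose receptor Mrc1 (3.43). MHC class II presentation rose by 2.43 with 4 of 5 called (4 adjusted over the list alone, adjusted p = 2.84e-05), including H2-Ab1 (3.54) and the invariant chain Cd74 (2.70). Fibroblast and matrix genes rose by 1.84 with 6 of 11 called (6 adjusted over the list alone, adjusted p = 4.46e-09), including lumican, Lum (3.00), and periostin, Postn (3.23). Interferon gamma targets rose by 1.41 with 4 of 8 called (adjusted p = 9.51e-06), including the chemokine Cxcl9 (2.85) and the GTPase Gbp2 (2.23). Smaller rises were found for mature neutrophil genes (1.13, 3 of 9 called, S100a9 at 2.75) and NK cell genes (1.11, 1 of 2, Klrd1 at 1.28). Further rises were those of type I interferon targets (1.08, 2 of 7, Oasl2 at 1.37), endothelial genes (1.06, 4 of 11, Cdh5 at 2.28 and Emcn at 1.93) and lymph node stroma genes (1.04, 3 of 6, Cxcl13 at 1.38). Markers of tissue next to the tumour also rose, with skeletal muscle genes at 0.96 (4 of 8 called, Tnnc2 at 1.70), keratinocyte genes at 0.80 (1 of 8 called) and adipocyte genes at 0.63 (0 of 7 called). For these lists the counts were the same when adjusted over the list alone. With an estimated correlation the adjusted p was 0.135 for skeletal muscle, 0.218 for keratinocytes and 0.082 for the other lists named so far.

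Relative to the median, regulatory T cell genes rose by 0.86 (0 of 4 called, Foxp3, Ctla4 and Ccr8 not being measured), cytotoxic lymphocyte genes by 0.78 (2 of 10, the granzymes Gzma at 1.18 and Gzmb at 1.79), T cell genes by 0.67 (1 of 9, Cd3g) and immune checkpoint genes by 0.64 (0 of 10). Megakaryocyte genes rose by 0.72 (1 of 6, Pf4), MHC class I presentation by 0.72 (1 of 8, the immunoproteasome subunit Psmb9 at 1.21, and by 0.79 without H2-Q10, which entered that list by a wrong match), dendritic cell genes by 0.62 (0 of 7) and mast cell genes by 0.52 (0 of 6). B cell genes (0.43), erythroid genes (0.39), neutrophil granule genes (0.39) and plasma cell genes (0.37) passed the list test with 0 members called. With an estimated correlation the adjusted p of these 12 lists lay between 0.082 and 0.232. Lists that did not pass at the preset correlation, nor with an estimated one, were pancreatic acinar (adjusted p = 0.057), melanocyte (0.0844), epithelial (0.0929), mesenchymal transition (0.207), hypoxia and glycolysis (0.261), germinal centre (0.419) and immediate early genes (0.79). For the last 6 the mean lay at or below 0 as fitted and above 0 relative to all genes, and the test pointed up.

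Falling lists were those of growth and biosynthesis. The amino acid stress list, targets of the transcription factor ATF4, fell to -1.23 relative to the median with 8 of 10 members called (8 adjusted over the list alone, adjusted p = 0.005). Its members included Atf4 itself (-1.92 before subtraction), Phgdh (-1.66) and Shmt2 (-1.69), enzymes of serine and glycine synthesis. Cell cycle genes shifted by -0.98 with 10 of 13 called (10 adjusted over the list alone, adjusted p = 0.000732), including Aurka (-1.70), Plk1 (-1.72) and the replication helicase subunit Mcm5 (-1.38). Cholesterol synthesis shifted by -0.85 with 6 of 9 called (6 adjusted over the list alone, adjusted p = 0.0153), including Fdps (-1.78), Lss (-1.45) and Sqle (-1.25). With an estimated correlation the adjusted p was 0.338, 0.344 and 0.424 for these 3 lists. After quantile normalisation the shifts were -0.92, -0.58 and -0.46, and the cholesterol list no longer passed. In total 1846 of 13863 genes were called, 283 higher and 1563 lower in tumours. The balance depended on scaling: with array medians subtracted 380 were higher and 928 lower, and after quantile normalisation 401 were higher and 112 lower, 395 of these genes being called in the main analysis too.

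**Figure D1:**
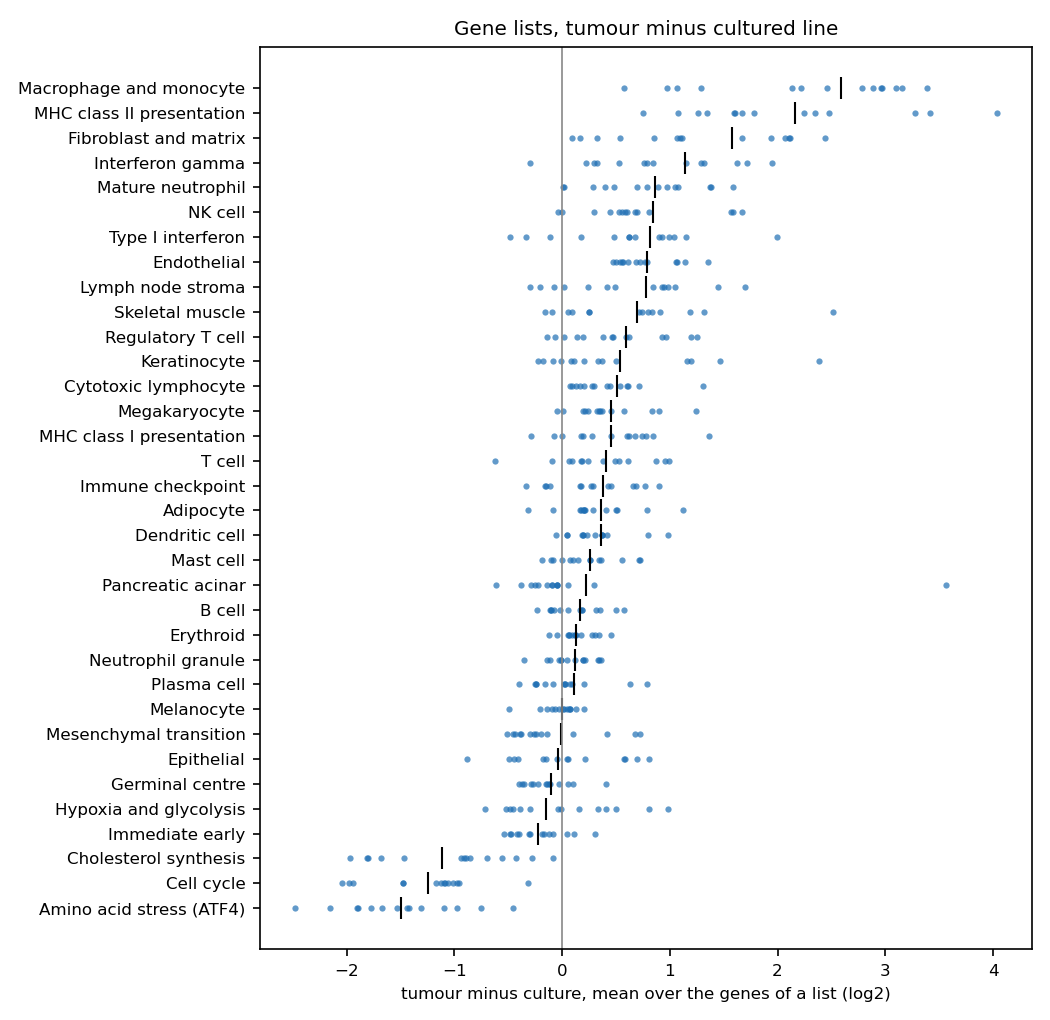
Mean log2 difference of each gene list between the tumours and the culture of a line. The vertical axis names the 34 lists, each dot is 1 of 14 lines and each tick is the mean over 10 families; the macrophage and monocyte list has its tick at 2.59 and the amino acid stress list at -1.49, before the median of -0.26 is subtracted.

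Tumours were then compared among the 15 models to find what sets each apart in the animal. Some of the genes that set a family apart are known from its tissue of origin. In the 20 B16 tumours the melanin enzymes Dct and Tyrp1 had means of 11.48 ± 0.13 and 11.33 ± 0.17 (SD, as for the family means that follow), against 4.01 over the other families for each. P815 tumours (n = 5) had Tph1, the serotonin synthesis enzyme of mast cells, at 9.86 ± 0.34 against 3.91, and the mast cell protease Cpa3 at 9.39 ± 0.64 against 4.33. PAN02 tumours (n = 4) had the acinar trypsin inhibitor Spink1 at 8.87 ± 2.81 against 3.08, a wide spread between mice, and Tspan8 at 10.52 ± 0.35 against 5.29, with TRAMP-C at 10.08. EL4 tumours had Rgs13 at 8.21 ± 0.66 against 2.35 and Timd2 at 8.80 ± 0.23 against 3.48. Renca tumours had the kidney brush border peptidase Mme at 9.86 ± 0.30 against 3.85. TRAMP-C tumours (n = 10) had the urothelial gene Upk1b at 9.94 ± 0.37 against 3.97. The Y-linked Eif2s3y was at 8.54 ± 0.30 against 2.16, also high in their cultures. H2-Ea, an MHC class II chain that is not transcribed in C57BL/6 mice, stood at 9.62 ± 0.37 in 4T1 and 9.93 ± 0.51 in Renca tumours, and the cytokine Tslp at 7.26 ± 0.28 in 4T1 against 2.95. MC38 tumours (n = 8) had Cntn3 at 8.06 ± 0.35 and Fmr1nb at 8.06 ± 0.24. CT26 tumours had Rpl39l at 7.85 ± 0.22 and Baiap2l1 at 9.67 ± 0.12. LL2 tumours had Apcdd1 at 9.37 ± 0.11 and the Wnt inhibitor Dkk2 at 9.57 ± 0.11, the latter level with TC1 (9.55). TC1 tumours had Neto2 at 8.84 ± 0.35 and Crabp1 at 12.32 ± 0.11. By the F test in limma 7252 of 13746 genes differed, and the adjusted p of the genes named here was at most 2.35e-12.

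Gene lists followed the same lines when each family was set against the mean of the others. In B16 tumours melanocyte genes were higher by 4.65 with 9 of 9 called (9 adjusted over the list alone, adjusted p = 1.68e-22, and 1.56e-07 with an estimated correlation). Macrophage and monocyte genes were lower in B16, at -1.82, with 9 of 11 called (adjusted p = 1.18e-09, and adjusted p = 0.0609 with an estimated correlation). Fibroblast and matrix genes (-1.61, 7 of 11 called) and MHC class II presentation (-1.43, 4 of 5 called) were also lower there, with adjusted p = 0.0805 and 0.185 with an estimated correlation. EL4 tumours were higher in T cell genes by 2.39 (6 of 9 called, adjusted p = 1.15e-12, and 0.000821 with an estimated correlation), including Cd3d (4.75) and Themis (3.37). P815 tumours were higher in mast cell genes by 1.94 (3 of 6, adjusted p = 0.000423, and 0.00527 with an estimated correlation), including the stem cell factor receptor Kit (4.73) and the transcription factor Gata2 (2.17). Their megakaryocyte genes were higher by 1.39 (3 of 6, adjusted p = 0.0213 with an estimated correlation). 4T1 tumours were higher in epithelial genes by 2.00 (7 of 9, adjusted p = 5.84e-13, and 0.00527 with an estimated correlation), including Krt18 (4.10) and Epcam (3.90). PAN02 tumours were higher in pancreatic acinar genes by 3.57 (5 of 5, adjusted p = 2.2e-09, and adjusted p = 0.0599 with an estimated correlation) and in MHC class II presentation by 1.74 (4 of 5, adjusted p = 0.0609 with an estimated correlation). The acinar mean was 9.71 and 11.9 in PAN02 tumours 3 and 4, 4.62 in the lowest PAN02 tumour and 4.33 in the PAN02 culture, so the acinar shift was not shared by all PAN02 tumours or by the cultured line. MC38 tumours were higher in type I interferon targets by 1.62 (5 of 7, adjusted p = 0.0643 with an estimated correlation) and amino acid stress genes by 1.04 (5 of 10, adjusted p = 0.0433 with an estimated correlation).

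TRAMP-C tumours were lower in cell cycle genes, at -0.85 with 4 of 13 called (adjusted p = 1.58e-12, and 0.0477 with an estimated correlation), and higher in fibroblast and matrix genes by 1.22 (8 of 11, adjusted p = 0.0609 with an estimated correlation). Keratinocyte genes, markers of skin, were higher in TRAMP-C by 1.25 (6 of 8, adjusted p = 0.485 with an estimated correlation) and in P815 by 1.99 (8 of 8, adjusted p = 0.404 with an estimated correlation). Keratinocyte means over 7 were found in 3 of the 10 TRAMP-C and 3 of the 5 P815 tumours. Renca tumours were higher in macrophage genes by 1.10 (6 of 11, adjusted p = 0.13 with an estimated correlation). TC1 tumours were higher in mesenchymal transition genes by 0.91 (5 of 9, adjusted p = 0.00295 with an estimated correlation), CT26 by 0.62 (1 of 9, adjusted p = 0.00617 with an estimated correlation), and EL4 lower, at -0.89 (4 of 9, adjusted p = 0.0131 with an estimated correlation). MHC class I presentation was lower in B16 (-0.94, 3 of 8), TC1 (-0.83, 2 of 8), LL2 (-0.70, 3 of 8) and TRAMP-C tumours (-0.44, 1 of 8), with adjusted p = 0.173, 0.16, 0.203 and 0.409 with an estimated correlation. Without the wrongly matched H2-Q10 these shifts were -1.04, -0.89, -0.74 and -0.48.

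**Figure D2:**
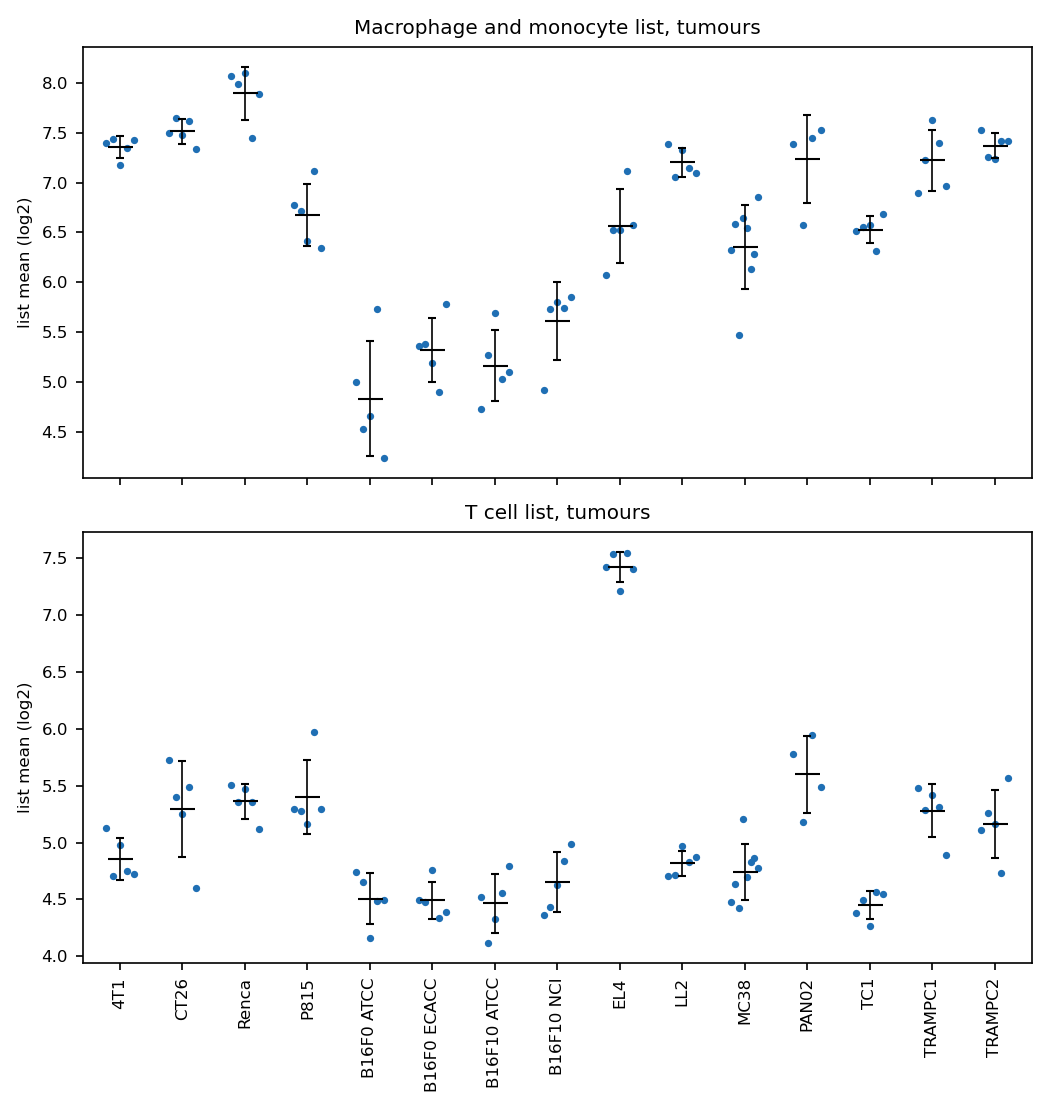
Mean log2 expression of the macrophage and monocyte list and of the T cell list in each tumour array, by model. Points are arrays and bars are the mean ± SD. Macrophage means of groups ran from 4.84 in B16F0 ATCC to 7.90 in Renca, and the T cell mean was 7.42 in EL4 against 5.60 in PAN02, the next highest group.

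Related tumours were compared in pairs. B16F10, a subline selected for lung colonisation, differed from B16F0 (n = 10 and 10) in 8 genes, 5 higher and 3 lower. Phyhipl was higher by 1.73 ± 0.17 (adjusted p = 4.81e-11), followed by Dcdc2a (1.35 ± 0.16), Bex1 (1.17 ± 0.17), the carbonic anhydrase related Car8 (1.08 ± 0.24) and the inflammasome adaptor Pycard (1.07 ± 0.15). The oocyte growth factor Gdf9 (-1.32 ± 0.29), the peptide hormone cholecystokinin, Cck (-1.09 ± 0.26), and the matrix link protein Hapln1 (-1.02 ± 0.17) were lower. After quantile normalisation 7 genes were higher and 1 lower, and without B16F10 NCI tumour 6 the count was 5. Each subline is represented by 2 stocks, and several of these genes also differed between stocks of the same subline, so a difference between sublines cannot be separated from differences between stocks. B16F10 from NCI exceeded B16F10 from ATCC (n = 5 and 5) in Bex1 by 2.60 ± 0.24 (adjusted p = 4.37e-12) and Phyhipl by 2.53 ± 0.24. It also exceeded ATCC in the interferon-inducible genes Psmb9 (1.77 ± 0.39), Bst2 (1.37 ± 0.27) and Trim34a (1.28 ± 0.27). Lower in NCI were Olfr1271 (-1.60 ± 0.39), the ubiquitin ligase Mgrn1 (-1.32 ± 0.13), Odf3l1 (-1.30 ± 0.26), Wdr18 (-1.21 ± 0.27) and Aldh1l2 (-1.12 ± 0.25). MHC class I presentation was higher in NCI by 0.80 with 2 of 8 called (adjusted p = 1.29e-08, and adjusted p = 0.0634 with an estimated correlation), and by 0.90 without the wrongly matched H2-Q10. The count of 17 genes (11 higher, 6 lower) was 6 in a fit to the compared groups only, 35 without B16F10 NCI tumour 1, and 11 without NCI tumour 5 or without NCI tumour 6.

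B16F0 from ECACC differed from B16F0 from ATCC (n = 5 and 5) in 65 genes, 46 higher and 19 lower. Cck was higher by 3.48 ± 0.37 (adjusted p = 2.6e-10), the monoacylglycerol lipase Mgll by 3.03 ± 0.27, Tgtp1, an interferon-induced GTPase, by 2.79 ± 0.66, Gdf9 by 2.43 ± 0.40 and Trim30a by 2.10 ± 0.35. Dcdc2a (-1.81 ± 0.23), Mlip (-1.68 ± 0.40), Tmeff1 (-1.56 ± 0.24), the monocarboxylate transporter Slc16a7 (-1.52 ± 0.31) and Tuba4a (-1.47 ± 0.27) were lower. MHC class II presentation was higher by 0.85 with 1 of 5 called (3 adjusted over the list alone, adjusted p = 0.00473, and adjusted p = 0.384 with an estimated correlation). Between TRAMPC2 and TRAMPC1 tumours limma called 0 genes, with 588 at an unadjusted p under 0.05. Skeletal muscle genes were higher in TRAMPC2 by 0.92 with 0 of 8 called (adjusted p = 0.000347, and adjusted p = 0.54 with an estimated correlation). Keratinocyte genes moved the same way without passing (0.46, adjusted p = 0.0792). The arrays rich in keratinocyte genes, TRAMPC1 tumour 30 and TRAMPC2 tumours 31 and 34, had muscle means of 8.12, 7.93 and 8.28, so neighbouring tissue is not separated from the lines here. Without TRAMPC2 tumour 33 the count was 2, and without tumours rich in keratinocyte or pancreatic genes it was 3.

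The colon carcinomas CT26 (n = 5) and MC38 (n = 8) differed in 778 genes, 387 higher and 391 lower in CT26, and their hosts are of different strains. H2-Ea was higher in CT26 by 5.51 ± 0.34, the adhesion gene Amigo2 by 5.48 ± 0.42, Baiap2l1 (identifier 66898, chromosome 5, 144264525 to 144358112) by 5.35 ± 0.14, Rpl39l by 5.09 ± 0.31 and the interferon-inducible Ifi202b by 4.89 ± 0.28. Fmr1nb (-4.89 ± 0.17), Cntn3 (-4.81 ± 0.12), Tex13b (-4.41 ± 0.19), Brinp3 (-3.95 ± 0.27) and Tmeff1 (-3.81 ± 0.21) were lower. Macrophage and monocyte genes were higher in CT26 by 1.16 with 7 of 11 called (7 adjusted over the list alone, adjusted p = 8.39e-07, and adjusted p = 0.187 with an estimated correlation). Type I interferon targets (-1.07, 4 of 7 called, adjusted p = 0.00674) and amino acid stress genes (-0.85, 3 of 10 called, adjusted p = 0.00118) were lower, with adjusted p = 0.54 and 0.292 with an estimated correlation.

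Draining lymph nodes of tumour-bearing mice (n = 72) were compared with nodes of mice without tumours of the same strain and sex (n = 20). Cell division genes rose. Mybl1, a transcription factor of dividing germinal centre B cells (identifier 17864, chromosome 1, 9667407 to 9700439), was higher by 1.84 ± 0.18 (adjusted p = 3.23e-12), the DNA topoisomerase Top2a by 1.55 ± 0.18 (adjusted p = 1.25e-09) and the proliferation antigen Mki67 by 1.47 ± 0.19. Shcbp1 (1.54 ± 0.20), Hmmr (1.53 ± 0.19), Cep55 (1.47 ± 0.14) and Nuf2 (1.45 ± 0.17), genes of mitosis and cytokinesis, and Eaf2 (1.46 ± 0.25) rose with them. The protease inhibitor Slpi was higher by 1.87 ± 0.28 and the chemokine Ccl12 by 1.78 ± 0.30. All 10 were higher against each of the 4 sets of controls, but the BALB/c nodes include the 6 low in B cell genes. Ccl12 rose by 2.85 in C57BL/6J females and by 0.52 to 0.79 against the other 3 sets. The 9 genes that fell, none of them on the adipocyte list, were the cytochrome oxidase subunit Cox8b (-1.93 ± 0.35), the fatty acid transporter Cd36 (-1.83 ± 0.29, adjusted p = 1.52e-06), the uncoupling protein Ucp1 (-1.62 ± 0.32), the carbonic anhydrase Car3 (-1.56 ± 0.46), Cdo1 (-1.48 ± 0.37), the kinase Pdk4 (-1.39 ± 0.24), Cidea (-1.33 ± 0.26), Amy1 (-1.16 ± 0.35) and Prkar2b (-1.12 ± 0.31). Cd36, Car3, Cdo1 and Amy1 were lower against all 4 sets of controls and the other 5 against 3 of 4. The exception was the male controls for Cox8b, Ucp1, Pdk4 and Cidea, and for Prkar2b the BALB/c controls (0.10).

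The cell cycle list rose by 0.96 with 6 of 13 called (6 adjusted over the list alone, adjusted p = 3.86e-22, and 0.0145 with an estimated correlation). Germinal centre genes rose by 0.66 with 2 of 6 called (Mybl1 and Rgs13, adjusted p = 0.00275). Plasma cell genes rose by 0.45 with 1 of 8 called (the antibody joining chain Jchain at 1.44, adjusted p = 0.0106). With an estimated correlation the adjusted p was 0.178 and 0.197. Adipocyte genes fell by 0.65 with 0 of 7 called (1 adjusted over the list alone, adjusted p = 0.00021, and adjusted p = 0.207 with an estimated correlation). Erythroid genes fell by 0.31 and endothelial genes by 0.21, each with adjusted p = 0.0234 with an estimated correlation and 0 members called. B cell genes (mean 0.09 while the test pointed down, adjusted p = 0.864) and T cell genes (-0.07, adjusted p = 0.289) did not pass. A total of 61 of 13469 genes were called, 52 higher and 9 lower, and 42 and 15 after quantile normalisation. Of the 92 nodes, 8 had B cell list means under 7, namely 6 of the BALB/c tumour models, 1 C57BL/6J female control and 1 DBA/2J control. Without the 6 the count was 39, without the 8 it was 22, without C57BL/6J female control 5 alone it was 33, and with the adipocyte list mean as a covariate it was 28.

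**Figure D3:**
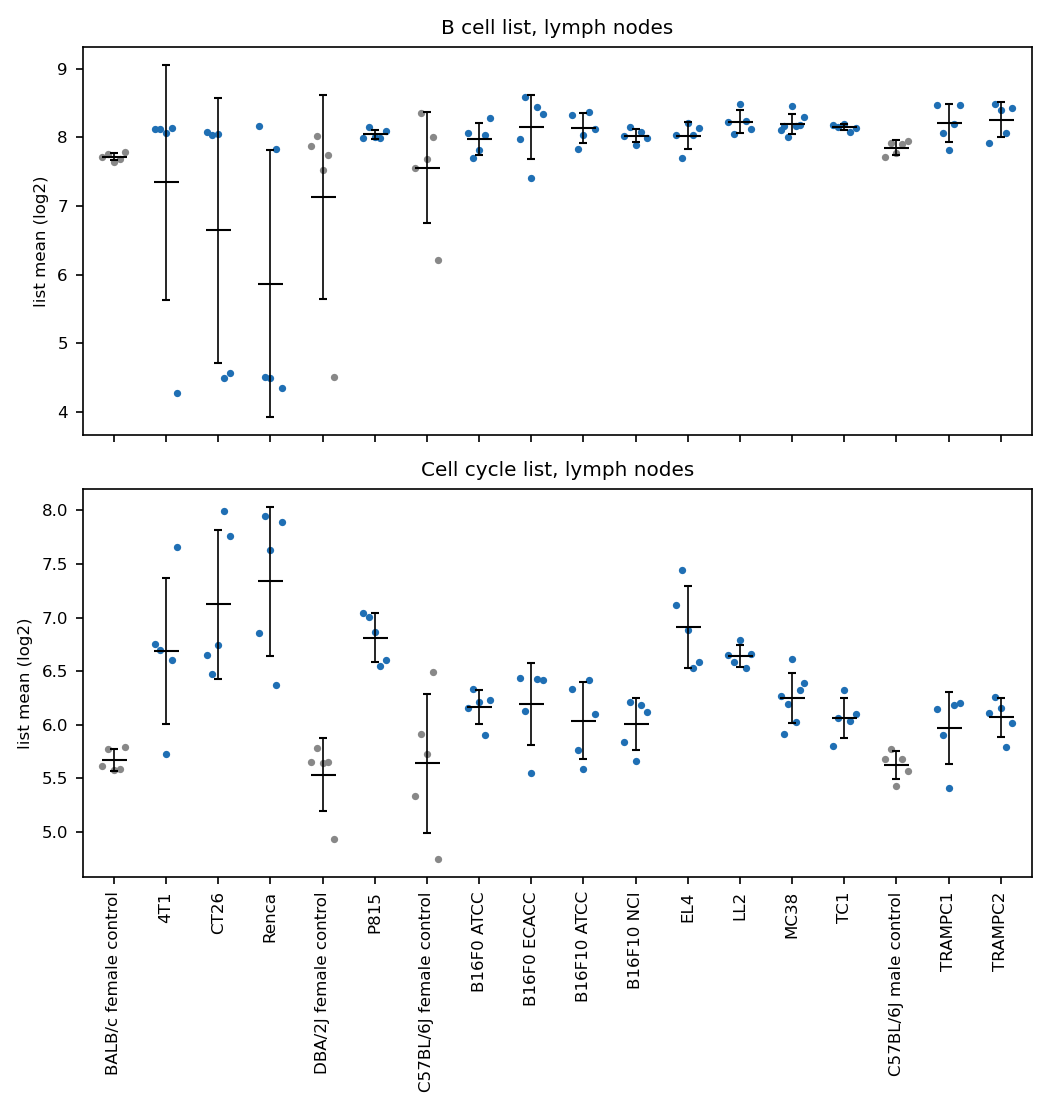
Mean log2 expression of the B cell list and of the cell cycle list in each lymph node, by group. Grey points are mice without tumours, blue points tumour-bearing mice, and bars the mean ± SD. In B cell genes 6 nodes of 4T1, CT26 and Renca lie between 4.28 and 4.57, while the lowest of the 84 nodes outside the 8 with low B cell means lies at 7.41.

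By model, BALB/c nodes showed the cell cycle change and, in the same groups, the nodes with few B cell transcripts. In 4T1 nodes Nuf2 (1.73 ± 0.37), Top2a (1.60 ± 0.39) and Cenpe (1.57 ± 0.36) rose and the sinus macrophage genes Marco (-1.74 ± 0.32) and Cd209b (-1.67 ± 0.43) and the clotting factor F8 (-1.54 ± 0.38) fell. The cell cycle list rose by 1.02 with 2 of 13 called (5 adjusted over the list alone, adjusted p = 0.0495 with an estimated correlation). In CT26 nodes Nuf2 (2.54 ± 0.37), Shcbp1 (2.52 ± 0.42) and the histone H1f5 (2.43 ± 0.29) rose, Cox8b (-2.33 ± 0.75), Timd4 (-2.07 ± 0.56) and Cd209b (-2.06 ± 0.43) fell. The cell cycle list rose by 1.46 with 11 of 13 called (adjusted p = 0.0575 with an estimated correlation). In Renca nodes the epithelial secretory gene Wfdc2 (3.65 ± 0.59), Tspan8 (3.43 ± 0.54) and the small heat shock protein Cryab (3.22 ± 0.43) rose and Ubd (-3.09 ± 0.65), Timd4 (-2.91 ± 0.56) and the T cell chromatin factor Satb1 (-2.84 ± 0.60) fell. B cell genes fell there by 1.85 with 7 of 8 called and T cell genes by 1.67 with 7 of 9 called (adjusted p = 0.269 and 0.215 with an estimated correlation). The cell cycle list rose by 1.67 with 11 of 13 called (adjusted p = 0.125 with an estimated correlation). Called genes numbered 32 in 4T1, 340 in CT26 and 1097 in Renca nodes. Without the 6 nodes low in B cell genes (4T1 node 36, CT26 nodes 28 and 29 and Renca nodes 21, 22 and 24), the counts were 22 in 4T1, 57 in CT26 and 8 in Renca. Without these 6, the Renca genes Wfdc2 (0.65), Tspan8 (0.44), Cryab (0.43), Timd4 (-0.66) and Satb1 (-0.07) lost their calls, and Ubd turned to 0.06. In CT26 Nuf2, Shcbp1 and H1f5 kept theirs, and Cox8b, Timd4 and Cd209b lost them. In 4T1 Nuf2 and Marco kept theirs, and Top2a, Cenpe, Cd209b and F8 lost them.

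Without the 8 nodes low in B cell genes the cell cycle list rose by 0.78 in 4T1, 0.96 in CT26 and 0.94 in Renca nodes (adjusted p = 0.0165, 0.0197 and 0.0242 with an estimated correlation). The Renca B cell list then stood at 0.28 and the T cell list at -0.11, and neither passed (adjusted p = 0.131 and 0.0961). Leaving out single arrays gave 12 (without 4T1 node 36) to 91 genes in 4T1, 126 to 595 in CT26 and 666 to 1665 in Renca nodes. A fit to only the 2 groups compared gave 28 in CT26, 231 in Renca and 0 by limma in 4T1, with 1032 at an unadjusted p under 0.05.

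In nodes of C57BL/6J females Ccl12 was among the 3 largest rises of 8 models, from 2.42 ± 0.63 in B16F0 ECACC to 3.18 ± 0.63 in B16F0 ATCC, all against the same 5 control nodes. Sfrp2, a secreted Wnt modulator, was named in 4 of them, from 1.77 ± 0.37 in B16F10 ATCC to 1.94 ± 0.37 in B16F10 NCI. LL2 nodes showed Jchain (3.09 ± 0.83) and Slpi (2.91 ± 0.60), MC38 nodes Mybl1 (2.08 ± 0.36) and Slpi (2.04 ± 0.56), and TC1 nodes the alarmin Il33 (1.86 ± 0.37). EL4 nodes showed the acute phase gene Saa3 (4.07 ± 0.56) and the mast cell protease Cpa3 (2.82 ± 0.34), a gene that EL4 tumours also expressed at 6.65. B16F0 ATCC nodes had Ubd (2.21 ± 0.65), B16F0 ECACC nodes Tgtp1 (1.77 ± 0.38) and the MHC class II chain H2-Aa (1.61 ± 0.28), B16F10 ATCC nodes the costimulator Icos (1.64 ± 0.45) and B16F10 NCI nodes Serpina10 (1.39 ± 0.30). Falls named in these models were Pdk4 in 6 models (from -1.98 ± 0.52 to -2.43 ± 0.52, and -2.01 ± 0.48 in MC38), Cd36 in 5 (from -2.07 ± 0.56 to -2.97 ± 0.61), Cox8b, Prkar2b, Cidea, the eosinophil chemokine receptor Ccr3, Gdpd2, Ptms and Slc27a2. Of all these genes only Slpi in LL2 and Saa3, Cpa3 and Cd36 in EL4 kept their calls against the male controls of the strain. There Ccl12 stood at 0.04 to 0.80 and Sfrp2 between -0.08 and 0.08, and Gdpd2 in B16F10 NCI turned to 0.03 and Slc27a2 in B16F0 ECACC to 0.21. The cell cycle list rose by 1.27 in EL4 (9 of 13 called) and by 1.00 in LL2 (5 of 13, 6 adjusted over the list alone). The adjusted p was 0.0991 and 0.156 with an estimated correlation. Plasma cell genes rose by 1.01 in LL2 (1 of 8, 2 adjusted over the list alone, adjusted p = 0.0264 with an estimated correlation).

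In these nodes called genes numbered 297 in EL4, 101 in LL2, 68 in B16F0 ATCC, 54 in MC38, 40 in B16F10 ATCC, 31 in B16F0 ECACC, 29 in B16F10 NCI and 21 in TC1. These counts rest on the shared controls: without control node 5 they were 168 in EL4, 23 in LL2, 18 in B16F0 ATCC, 17 in MC38, 9 in B16F10 ATCC, 12 in B16F0 ECACC and 14 in B16F10 NCI. Without control node 3 they were 180 in LL2, 146 in B16F0 ATCC, 105 in MC38, 109 in B16F10 ATCC, 75 in B16F0 ECACC, 60 in B16F10 NCI and 66 in TC1. A fit to only the 2 groups compared gave 137 in EL4, 12 in LL2, 3 in MC38 and 0 by limma in the other 5, with 1075 to 1900 genes at an unadjusted p under 0.05. Against the male controls of the strain, chosen after seeing the data, 175 genes were called in EL4, 26 in LL2, 3 in MC38 and 2 in each of the other 5 models. In MC38 and these 5 models 0 of the genes called against males by limma were higher in tumour-bearing mice, with 280 to 1102 genes at an unadjusted p under 0.05. The 2 genes called in each of the 5 were the Y-linked Kdm5d and Eif2s3y, which separate the sexes on every array. Without them 173 were left in EL4, 24 in LL2 and 1 in MC38.

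P815 nodes of DBA/2J mice showed higher germinal centre and cell cycle genes, with Rgs13 higher by 3.54 ± 0.83, Jchain by 3.52 ± 0.83 and Eaf2 by 2.92 ± 0.52. The germinal centre list rose by 1.60 with 3 of 6 called (3 adjusted over the list alone, adjusted p = 1.58e-08, and 0.024 with an estimated correlation) and the cell cycle list by 1.28 with 8 of 13 called (adjusted p = 0.0257 with an estimated correlation). Plasma cell genes rose by 0.90 with 2 of 8 called (adjusted p = 8.16e-05, and adjusted p = 0.0537 with an estimated correlation). The call of Rgs13 was lost without DBA/2J control node 5 alone. Without the 8 nodes low in B cell genes, that control among them, the germinal centre list rose by 1.48, the cell cycle list by 1.13 and the plasma cell list by 0.89 (adjusted p = 0.00299, 0.00299 and 0.017 with an estimated correlation). Rgs13 then stood at 3.26, Jchain at 3.60 and Eaf2 at 2.91, each still called. Adipocyte genes fell by 1.95 with 5 of 7 called (adjusted p = 0.0639 with an estimated correlation), and the largest single falls were Rbp7 (-3.73 ± 0.35), Cxcl15 (-3.42 ± 0.45) and Car3 (-3.30 ± 0.98). Of 288 called genes, 93 were higher and 195 lower. The count was 71 without DBA/2J control node 5, whose adipocyte mean was 9.37, B cell mean 4.50 (nearest other control 7.53) and cell cycle mean 4.93 (nearest 5.64), and 11 with the adipocyte covariate, under which Car3 stood at 0.83. In C57BL/6J males limma called 0 genes in TRAMPC1 nodes, with 328 at an unadjusted p under 0.05. In TRAMPC2 nodes the methyltransferase Inmt was the only called gene, lower by 1.37 on the log2 scale (log2 fold change -1.37 ± 0.27, adjusted p = 0.0395), and the call was lost when any of 8 single arrays was left out.

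Spleens of tumour-bearing mice (n = 78) were compared with spleens of mice without tumours (n = 20). Genes of neutrophil granules and of red cell precursors were higher on average over the 11 families. The neutrophil granule protein Ngp (identifier 18054, chromosome 9, 110419808 to 110423012) rose by 2.36 ± 0.28 (adjusted p = 1.59e-08), and the calprotectin subunits S100a8 and S100a9 by 2.18 ± 0.30 and 2.14 ± 0.29. Red cell genes rose with them, namely Hemgn (1.93 ± 0.36), the anion exchanger Slc4a1 (1.71 ± 0.32), the carbonic anhydrase Car2 (1.70 ± 0.34), Rhag (1.65 ± 0.33) and the Kell antigen Kel (1.61 ± 0.31), as did Tspan8 (2.15 ± 0.36) and the protease Ctse (1.52 ± 0.26). These rises were not shared by all hosts. Against C57BL/6J female controls the 10 genes were higher by 2.93 to 3.96, and against BALB/c controls 9 of the 10 were higher, by 0.25 to 3.11, with Ctse at 0. Against C57BL/6J male and DBA/2J controls all 10 were lower, with Ngp at -1.54 and -0.44. In all 31 of 13414 genes were called, 31 higher and 0 lower in limma, and 2233 had an unadjusted p under 0.05. With families as replicates the count was 8, and without C57BL/6J female control spleen 2 it was 59.

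The erythroid list rose by 1.18 with 5 of 7 called (5 adjusted over the list alone, adjusted p = 1.29e-13, and 0.00684 with an estimated correlation), from 2.30 ± 0.42 in C57BL/6J females and 0.18 ± 0.59 in BALB/c to -0.40 ± 0.52 in DBA/2J and -0.92 ± 0.50 in C57BL/6J males. The controls themselves differed in this list, with means of 4.98 ± 0.92 (SD, n = 5) in C57BL/6J females, 6.09 ± 0.98 in males, 6.84 ± 1.31 in BALB/c and 7.39 ± 0.99 in DBA/2J. Neutrophil granule genes rose by 0.94 with 4 of 10 called (adjusted p = 1.12e-21, and 0.000192 with an estimated correlation), from 1.31 ± 0.17 in C57BL/6J females and 1.09 ± 0.17 in BALB/c to -0.12 ± 0.28 in DBA/2J and -0.64 ± 0.17 in males. In the C57BL/6J female models, set against the male controls, the neutrophil granule shift went from 2.65 to 2.12 in EL4, 1.68 to 1.16 in PAN02, 1.44 to 0.92 in LL2, 0.99 to 0.47 in MC38, 0.72 to 0.20 in TC1 and 0.70 to 0.18 in B16F10 ATCC. It turned negative in B16F0 ATCC (0.41 to -0.11), B16F0 ECACC (0.23 to -0.29) and B16F10 NCI (0.14 to -0.39). Mature neutrophil genes rose by 0.84 (3 of 9 called) and megakaryocyte genes by 0.57 (1 of 6, the platelet chemokine Ppbp at 1.19). Cell cycle genes rose by 0.70 (2 of 13). The adjusted p was 0.00323, 0.00561 and 0.0497 with an estimated correlation. T cell genes fell by 0.39 with 0 of 9 called (adjusted p = 1.1e-13, and 0.00323 with an estimated correlation) and the 4 measured genes of the regulatory T cell list, Il2ra, Ikzf2, Tnfrsf18 and Tnfrsf4, by 0.24 (0 of 4, adjusted p = 0.0497 with an estimated correlation). Foxp3, Ctla4 and Ccr8 were not measured. These lists turned between hosts too. In C57BL/6J females, BALB/c, DBA/2J and males, in that order, mature neutrophil genes shifted by 1.17, 0.96, -0.07 and -0.61, megakaryocyte genes by 0.73, 0.65, 0.03 and -0.12, cell cycle genes by 1.36, 0.01, -0.34 and -0.21, and T cell genes by -0.70, -0.14, 0.16 and 0.15. Pancreatic acinar genes, a sign of adjoining pancreas, were over a list mean of 6 in 15 spleens, and without these the overall count was 20.

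**Figure D4:**
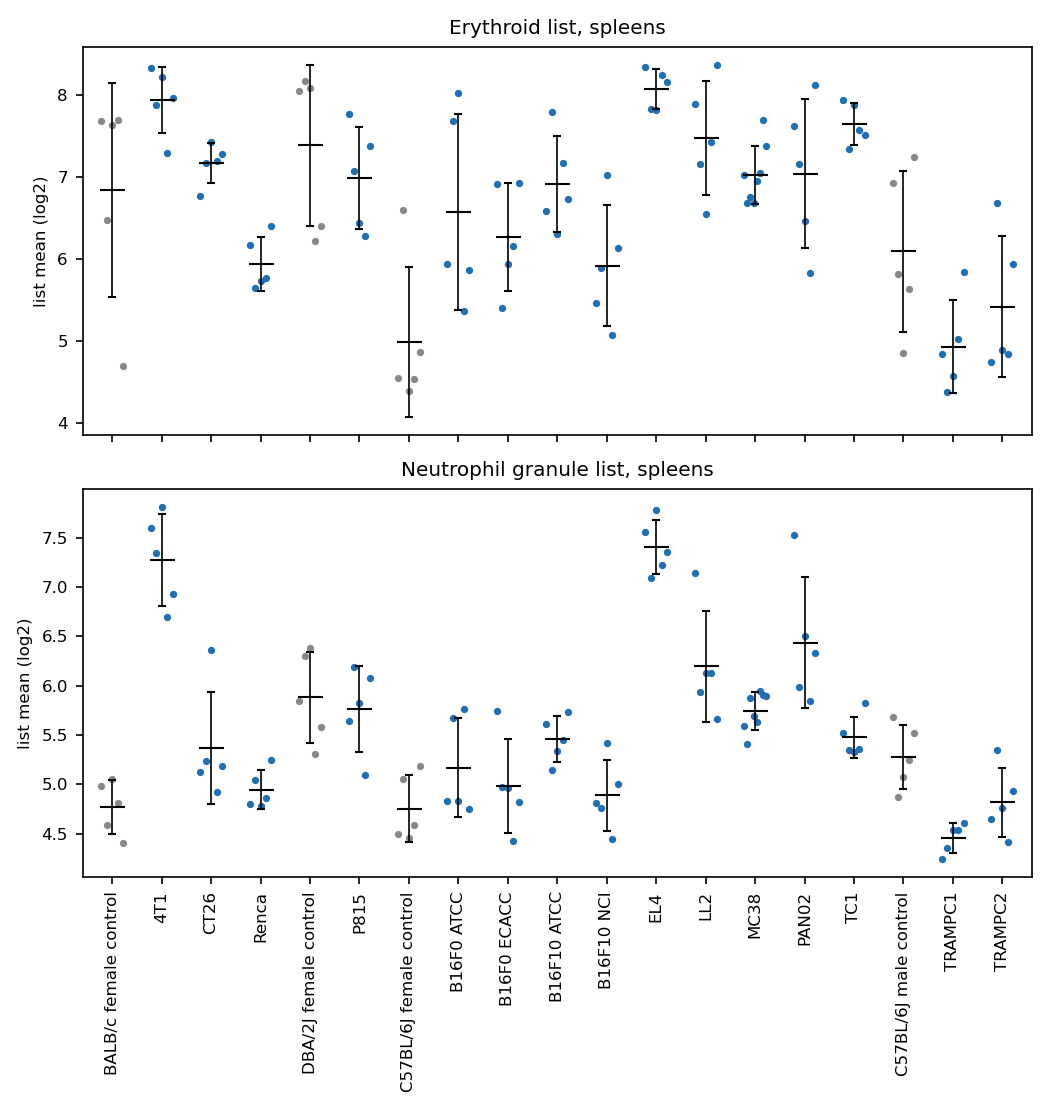
Mean log2 expression of the erythroid list and of the neutrophil granule list in each spleen, by group. Grey points are mice without tumours, blue points tumour-bearing mice, and bars the mean ± SD. The erythroid mean is 4.98 in C57BL/6J female controls and 8.08 in EL4, and the neutrophil granule mean is 4.77 in BALB/c controls and 7.28 in 4T1.

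4T1 spleens held the strongest neutrophil change in BALB/c hosts, with Ngp higher by 5.20 ± 0.59 (adjusted p = 2.29e-10), S100a8 by 4.39 ± 0.61 and S100a9 by 3.99 ± 0.60. All 10 of 10 neutrophil granule genes were called (10 adjusted over the list alone), with a list shift of 2.50 (adjusted p = 1.33e-36, and 4.29e-06 with an estimated correlation), including myeloperoxidase, Mpo (3.05), and lactoferrin, Ltf (2.66). The receptors Olfr223 (-1.36 ± 0.29), Olfr1342 (-1.29 ± 0.32) and Tas2r136 (-1.27 ± 0.29) fell. CT26 spleens showed Ngp at 2.58 ± 0.59, Jchain at 1.49 ± 0.41 and Ppbp at 1.45 ± 0.39, with Cirbp (-1.38 ± 0.20), Nmbr (-1.16 ± 0.24) and Mb (-1.07 ± 0.26) lower. In Renca spleens Sycp1 (1.26 ± 0.21), Scn7a (1.24 ± 0.23) and Rps15a (1.24 ± 0.28) rose and the histone genes H4c14 (-1.99 ± 0.55), H1f5 (-1.75 ± 0.49) and H4c12 (-1.63 ± 0.41) fell. The cell cycle list fell there by 0.90 with 0 of 13 called (5 adjusted over the list alone, adjusted p = 0.243 with an estimated correlation). The counts were 84 in 4T1, 23 in CT26 and 29 in Renca, and leaving out single arrays gave 53 to 151, 12 to 60 and 12 to 83.

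In C57BL/6J females the red cell and neutrophil changes were largest in EL4, where S100a8 rose by 5.09 ± 0.61, Ngp by 5.00 ± 0.59 and Tspan8 by 4.62 ± 0.75. EL4 erythroid genes rose by 3.10 with 7 of 7 called and neutrophil granule genes by 2.65 with 8 of 10. Cell cycle genes rose there by 1.97 with 13 of 13 called. The adjusted p was 0.0352, 0.000151 and 0.0851 with an estimated correlation. Pancreatic acinar genes rose in the same spleens by 2.15 with 2 of 5 called (5 adjusted over the list alone, adjusted p = 0.442 with an estimated correlation). Erythroid genes also rose in TC1 by 2.67 and LL2 by 2.50 (7 of 7 each, adjusted p = 0.0171 and 0.0282 with an estimated correlation). They rose in PAN02 by 2.06 and MC38 by 2.04 (5 of 7 each, adjusted p = 0.0851 and 0.0489 with an estimated correlation). When the male controls of the strain were used, the erythroid shifts were 1.99 in EL4 (6 of 7 called), 1.56 in TC1, 1.39 in LL2, 0.95 in PAN02 and 0.93 in MC38, with 0 of 7 called in the last 4 (by limma, where 991 to 1842 genes had an unadjusted p under 0.05). Tspan8 and Hemgn were the largest rises in TC1 (4.48 ± 0.75 and 4.19 ± 0.75), LL2 (4.03 ± 0.75 and 3.96 ± 0.75) and MC38 (3.73 ± 0.68 and 3.60 ± 0.67), and Tspan8 (3.06 ± 0.75), Car2 (2.92 ± 0.71) and Hemgn (2.90 ± 0.75) in B16F10 ATCC. PAN02 spleens showed Tspan8 at 4.90 ± 0.75, Ngp at 4.04 ± 0.59 and S100a9 at 3.95 ± 0.60. T cell genes fell in PAN02 by 1.08 with 4 of 9 called (Cd3g at -1.77 ± 0.27, adjusted p = 0.000771 with an estimated correlation) and in EL4 by 0.81 with 3 of 9 (adjusted p = 0.0489 with an estimated correlation). Of the genes named in these spleens, S100a8, Ngp, Tspan8 and St8sia1 in EL4, Tspan8, Ngp, S100a9 and Cd3g in PAN02 and Fzd10 in B16F10 NCI kept their calls against the male controls, and the others lost them.

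Other falls in these spleens were of Cdo1 (from -1.49 ± 0.37 in B16F10 ATCC to -1.94 ± 0.37 in PAN02, and -0.39 to 0.05 against the male controls in the 6 models where it was named), the interferon-inducible Ubd (-1.76 ± 0.55 in LL2 and -1.62 ± 0.55 in EL4), Ccl12 (-1.44 ± 0.45 in LL2 and -1.52 ± 0.45 in TC1), Ccl8 (-1.08 ± 0.30 in MC38), H2-M2, and in EL4 Rgs5 (-1.51 ± 0.39) and St8sia1 (-1.46 ± 0.30). The fat genes Adipoq (-1.83 ± 0.50) and Car3 (-1.83 ± 0.40) fell in B16F10 NCI spleens, where Fzd10 (1.11 ± 0.26) and the erythroid factor Klf1 (1.08 ± 0.28) rose. B16F0 ATCC spleens had Gpx1 (1.53 ± 0.34), H2ac12 and H2ac15 higher and Cdo1 (-1.84 ± 0.37), Me1 and Ghr lower. Called genes numbered 498 in EL4, 277 in TC1, 267 in LL2, 254 in PAN02, 148 in MC38, 52 in B16F10 ATCC, 25 in B16F10 NCI and 8 in B16F0 ATCC. In B16F0 ECACC limma called 0, with 925 at an unadjusted p under 0.05. Against the male controls of the strain, an alternative chosen after seeing the data, the counts were 347 in EL4, 92 in PAN02, 25 in LL2, 7 in TC1, 4 in MC38, 4 in B16F10 ATCC, 8 in B16F10 NCI, 2 in B16F0 ATCC and 2 in B16F0 ECACC. Kdm5d and Eif2s3y make up 2 of each of these counts. Without spleens rich in pancreatic genes they were 240 in EL4, 78 in LL2, 85 in B16F10 NCI, 6 in B16F0 ECACC and 0 by limma in B16F10 ATCC, with 1561 at an unadjusted p under 0.05. Leaving out single arrays gave 1 to 151 in B16F10 ATCC, 41 to 227 in MC38, 85 to 339 in LL2, 136 to 354 in PAN02, 197 to 361 in TC1, 444 to 549 in EL4, 6 to 64 in B16F10 NCI, 0 to 33 in B16F0 ATCC and 0 to 11 in B16F0 ECACC by limma. In the 2 B16F0 ATCC runs with 0, 1144 and 1209 genes had an unadjusted p under 0.05. MC38 animals 56 to 59 alone gave 15. A fit to only the 2 groups compared gave 162 in LL2, 101 in PAN02 and 0 by limma in B16F10 ATCC, B16F10 NCI and B16F0 ATCC, with 1255 to 1831 at an unadjusted p under 0.05.

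In C57BL/6J males Gzma, a granzyme of cytotoxic lymphocytes, was the only called gene in spleens of TRAMPC1 (-1.75 ± 0.35, adjusted p = 0.0483) and TRAMPC2 (-1.83 ± 0.35, adjusted p = 0.0187), against the same 5 controls. In TRAMPC1 the neutrophil granule list fell by 0.82 with 0 of 10 called (2 adjusted over the list alone, adjusted p = 0.0317 with an estimated correlation) and the erythroid list by 1.17 with 0 of 7 called (5 adjusted over the list alone, adjusted p = 0.111 with an estimated correlation). In P815 spleens of DBA/2J mice Neto1 was the only called gene (-1.54 ± 0.21, adjusted p = 1.49e-06). The Gzma calls were each lost when single arrays were left out.

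The difference of the effects in the organs, node minus spleen, was tested directly. The highest differences were 2.39 ± 0.37 for Ccl12, 1.69 ± 0.26 for Sfrp2, 1.57 ± 0.25 for Mybl1, 1.41 for the chemokine Ccl8, 1.32 for Cep55, 1.26 for Msr1, 1.22 for podoplanin, Pdpn, 1.13 for Eaf2, 1.12 for Icos and 1.08 for Slpi. The spleen effect was below 0 for 6 of these genes, namely Ccl12 (1.78 in nodes, -0.61 in spleens), Sfrp2 (0.94, -0.75), Ccl8 (1.01, -0.40), Icos (0.66, -0.46), Pdpn (0.95, -0.27) and Msr1 (1.09, -0.17). The node effect of Ccl12 was 2.85 against C57BL/6J female controls and 0.52 to 0.79 against the other 3 sets. In nodes of C57BL/6J females neither Ccl12 nor Sfrp2 kept a call against the male controls, and the difference between organs was not tested against those. The neutrophil genes Ngp (-2.63 ± 0.38), S100a9 (-2.38) and S100a8 (-2.33), the red cell genes Hemgn (-2.13) and Alas2 (-1.87), with Car2 and Slc4a1 at -2.0 each, and Cd36 (-2.18), Tspan8 (-1.93) and Prkar2b (-1.92) had the lowest differences. In spleens Ngp, S100a8, S100a9, Hemgn, Car2, Slc4a1 and Tspan8 were all lower against C57BL/6J male and DBA/2J controls. Nodes low in B cell genes were kept in this comparison. Erythroid genes differed by -1.40 (5 of 7 called, adjusted p = 0.00047) and neutrophil granule genes by -0.98 (4 of 10, adjusted p = 0.000123). Mature neutrophil genes differed by -0.88 (3 of 9, adjusted p = 0.00129) and megakaryocyte genes by -0.81 (2 of 6, adjusted p = 0.000123). Germinal centre genes differed by 0.66 (1 of 6, adjusted p = 0.0363). These list tests used an estimated correlation between genes. In all 67 of 13757 genes were called, 12 with a positive and 55 with a negative difference. With the animal as a replicate block the same 67 genes were called.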

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

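The tests that weigh explanations in this part were chosen after the patterns were seen, the adipocyte covariate among them, though its possible outcomes were written down before it was run.

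A single array stood far from the others of its group in 9 of 156 group and list combinations tested, where chance gives about 1 in 20, or 7.8. Among tumours, the macrophage and monocyte mean was 4.93 in B16F10 NCI tumour 1 (nearest other array 5.74) and 6.58 in PAN02 tumour 3 (nearest 7.39). The T cell mean was 5.97 in P815 tumour 29 (nearest 5.30), and the MHC class I mean was 6.98 in CT26 tumour 29 (nearest 7.59). Among nodes, the B cell mean was 4.28 in 4T1 node 36 (nearest 8.06). DBA/2J control node 5 had a B cell mean of 4.50 (nearest 7.53) and a cell cycle mean of 4.93 (nearest 5.64). Among spleens, the erythroid mean was 6.60 in C57BL/6J female control 2 (nearest 4.86), and the neutrophil granule mean was 6.36 in CT26 spleen 27 (nearest 5.24).

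Averaged over hosts, the responses of nodes and spleens differed in 67 genes, tested directly. The difference was positive for Ccl12 (2.39), Sfrp2 (1.69), Mybl1 (1.57), Ccl8 (1.41), Cep55 (1.32), Msr1 (1.26), Pdpn (1.22), Eaf2 (1.13), Icos (1.12) and Slpi (1.08). It was negative for Ngp (-2.63), S100a9 (-2.38), S100a8 (-2.33), Cd36 (-2.18), Hemgn (-2.13), Car2 (-2.0), Slc4a1 (-2.0), Tspan8 (-1.93), Prkar2b (-1.92) and Alas2 (-1.87).

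The cultures of Hepa1-6 and ID8 enter no comparison, and genes there exceeded the highest of the 15 other cultures. In Hepa1-6, from liver, these were Tmem252 (9.88, highest other 5.49), albumin, Alb (8.96, 4.62), alpha-fetoprotein, Afp (8.72, 4.66), Akr1c19 (7.44, 3.52) and Habp2 (8.51, 4.83). In ID8, from ovary, they were Cd55 (8.93, 4.48), Prss35 (6.87, 4.59), Slc9a7 (6.70, 4.56), Slc7a2 (6.72, 4.59) and Mal2 (9.48, 7.36).

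The first pattern weighed is the lack of B cell transcripts on 6 node arrays, 4T1 node 36, CT26 nodes 28 and 29 and Renca nodes 21, 22 and 24. All 6 correlated best with the mean of their own model's tumours, as tumour tissue on the array would give. An exchange of tumour and node within an animal is argued against by the tumours of these animals, whose highest B cell mean was 4.57, and poor quality by the lowest best correlation of 0.962. Overgrowth of the node by tumour cells cannot be told apart from tumour tissue taken as a node, since 2 of the 6 had a B cell mean above every tumour of the model and the others did not. Metastasis to the node is a biological form of that overgrowth and stays open.

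The second pattern is the fall of 9 genes, Cox8b, Cd36 and Ucp1 among them and none on the adipocyte list, in nodes of tumour-bearing mice. More fat tissue on the control arrays may account for much of it, because with the adipocyte list mean as a covariate 3 of the 9 called falls stayed called and their median moved from -1.48 to -0.70. Without the nodes low in B cell genes 4 stayed called, with a median of -0.94, so control nodes low in lymphocyte transcripts are a candidate source too. The control nodes with few B cell transcripts were C57BL/6J female control 5 (B cell mean 6.21, adipocyte mean 7.57) and DBA/2J control 5 (4.50 and 9.37). No biological explanation was tested.

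The third pattern is the rise of erythroid genes in spleens of C57BL/6J female models. Low values of the shared female controls do not account for all of the rise in EL4, where 6 erythroid genes were also called higher than in the male controls of the strain, but its shift went from 3.10 to 1.99 against them, and among the other 8 models 0 had such a gene. Against the males the erythroid shift went from 2.67 to 1.56 in TC1, 2.50 to 1.39 in LL2, 2.06 to 0.95 in PAN02, 2.04 to 0.93 in MC38 and 0.93 to -0.18 in B16F10 NCI, and it stayed above 0 in 7 of the 8, all against the same 5 controls. For these models the female controls may be part of the source, and the rest stays open. A lower share of lymphocytes would raise the endothelial list too, and that list moved by -0.142. A shift common to all later arrays is argued against as the whole source. In the other hosts the shift lay between -0.922 ± 0.496 and 0.178 ± 0.591. A smaller common shift or an order effect within a strain was not tested. Red cell formation in the spleen stays open as a biological explanation for EL4.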

How the results depend on the processing

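Alternatives that left out arrays chosen by marker genes or by MC38 animal number, that used the male controls, or that took the adipocyte covariate were chosen after seeing the data, and so were the repeats of the list tests after quantile normalisation, without H2-Q10 and without the 8 nodes low in B cell genes. The cause of a change was not tested unless it is named.

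With the alternatives fixed in advance, arrays left out in turn aside, 43 counts moved by more than 1.5 times and 103 did not, and with the added ones 41 moved and 44 did not. No fold change minimum, which admits more genes by construction, gave 7199 genes for tumour against culture, 90 for B16F10 against B16F0, 56 for B16F10 NCI against ATCC, 167 for B16F0 ECACC against ATCC, 3211 for CT26 against MC38, 2169 for nodes of all models, 699 for spleens of all models and 660 for the difference between organs. No filter gave 39 in B16F10 NCI spleens and 2 in TRAMPC1 spleens. Quantile normalisation again gave 513 for tumour against culture. A fit to the compared groups only gave 6 for B16F10 NCI against ATCC. Equal weight per model gave 35 for nodes and 19 for spleens of all models. BALB/c models only gave 296 for nodes and 15 for spleens, C57BL/6J models only gave 143 for spleens, and families as replicates gave 8 for spleens.

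A fit to only the 2 groups compared, which estimates the spread from fewer samples, gave 231 genes in Renca nodes, 137 in EL4, 96 in P815, 28 in CT26, 12 in LL2, 3 in MC38 and 2 in TRAMPC2 nodes. It gave 0 in nodes of 4T1, B16F10 ATCC, B16F10 NCI, B16F0 ATCC, B16F0 ECACC and TC1. In spleens it gave 162 in LL2, 101 in PAN02, 28 in 4T1 and 4 in Renca, and 0 in B16F10 ATCC, B16F10 NCI, CT26, B16F0 ATCC, TRAMPC1, TRAMPC2 and P815. For these 13 counts of 0 by limma, 511 to 1900 genes had an unadjusted p under 0.05.

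Without the 6 nodes of tumour-bearing mice low in B cell genes the counts were 39 for nodes of all models, 57 in CT26 and 8 in Renca. Without the 8 nodes low in B cell genes they were 22 for all models, 70 in CT26, 66 in LL2, 32 in MC38, 26 in Renca, 33 in TC1 and 147 in P815. With the adipocyte covariate they were 28 for all models, 61 in LL2, 30 in B16F0 ATCC and 11 in P815 nodes. Without the 15 spleens rich in pancreatic genes the counts were 20 for spleens of all models, 85 in B16F10 NCI, 78 in LL2, 6 in B16F0 ECACC, 240 in EL4, and 0 by limma in B16F10 ATCC, TRAMPC1 and TRAMPC2, with 271 to 1561 at an unadjusted p under 0.05. Without the 9 tumours rich in genes of neighbouring tissue TRAMPC2 against TRAMPC1 gave 3. MC38 animals 56 to 59 alone gave 22 in nodes and 15 in spleens.

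Against the male controls, which also differ in sex from the tumour-bearing mice, nodes gave 175 genes in EL4, 26 in LL2, 3 in MC38 and 2 each in B16F10 ATCC, B16F10 NCI, B16F0 ATCC, B16F0 ECACC and TC1. Spleens gave 92 in PAN02, 25 in LL2, 8 in B16F10 NCI, 7 in TC1, 4 each in MC38 and B16F10 ATCC, and 2 each in B16F0 ATCC and B16F0 ECACC. The Y-linked Kdm5d and Eif2s3y make up 2 of each of these counts.

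Of 1666 gene list shifts 458 passed, and with an estimated correlation 58 of them. Without a filter 473 passed, with array medians subtracted 439, and after quantile normalisation 418, of which 402 were shared, and without the wrongly matched H2-Q10 467. Without H2-Q10 the MHC class I list also passed in nodes of all models (0.23, adjusted p = 0.0115, against 0.14 and 0.0902 with it), in nodes of LL2 (0.32), MC38 (0.36), TRAMPC2 (0.18), EL4 (0.39) and TC1 (0.31), in B16F0 ECACC spleens (0.21) and for B16F0 ECACC against ATCC tumours (0.47). Without the 8 nodes low in B cell genes 7 lists reversed. In CT26 nodes these were T cell (0.14), regulatory T cell (0.23), B cell (0.33) and MHC class II presentation (0.019), and in Renca nodes B cell (0.28), macrophage and monocyte (-0.16) and interferon gamma (0.076).

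Direction reversed for Prkar2b in nodes of all models with BALB/c models only (0.10) and for Ubd in Renca nodes without the 6 or the 8 nodes (0.061 in each). Against male controls it reversed for Sfrp2 in B16F10 ATCC nodes (-0.084), Gdpd2 in B16F10 NCI nodes (0.027), Slc27a2 in B16F0 ECACC nodes (0.21), and Cdo1 in spleens of B16F10 ATCC (0.052) and TC1 (0.031). With the adipocyte covariate Car3 in P815 nodes stood at 0.83. The cause was not tested.

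Leaving out each array (each family for tumour against culture) gave lowest and highest counts of 1681 and 1948 for tumour against culture, 7117 and 7434 for tumours among models, 5 and 12 for B16F10 against B16F0, 11 and 35 for B16F10 NCI against ATCC, 55 and 72 for B16F0 ECACC against ATCC, 0 and 2 for TRAMPC2 against TRAMPC1, 752 and 833 for CT26 against MC38, 33 and 91 for nodes of all models, 21 and 59 for spleens of all models, and 53 and 82 for the difference between organs. In nodes they were 12 and 91 (4T1), 126 and 595 (CT26), 666 and 1665 (Renca), 71 and 394 (P815), 18 and 146 (B16F0 ATCC), 10 and 79 (B16F0 ECACC), 9 and 109 (B16F10 ATCC), 14 and 60 (B16F10 NCI), 23 and 194 (LL2), 17 and 105 (MC38), 168 and 398 (EL4), 14 and 66 (TC1), 0 and 0 (TRAMPC1) and 0 and 1 (TRAMPC2). In spleens they were 53 and 151 (4T1), 12 and 60 (CT26), 12 and 83 (Renca), 1 and 1 (P815), 0 and 33 (B16F0 ATCC), 0 and 11 (B16F0 ECACC), 1 and 151 (B16F10 ATCC), 6 and 64 (B16F10 NCI), 85 and 339 (LL2), 41 and 227 (MC38), 444 and 549 (EL4), 136 and 354 (PAN02), 197 and 361 (TC1), and 0 and 1 in TRAMPC1 and in TRAMPC2. Of these runs 123 moved a count by more than 1.5 times and 1024 did not. Of 247 named genes 148 kept their call in every run, 99 lost it in at least 1, and 0 reversed.

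The arrays that moved a count, with the count without each, were these among controls. C57BL/6J female node 5 gave 33 for nodes of all models, 9 in B16F10 ATCC, 14 in B16F10 NCI, 23 in LL2, 17 in MC38, 18 in B16F0 ATCC, 12 in B16F0 ECACC and 168 in EL4. Node 3 gave 109 in B16F10 ATCC, 60 in B16F10 NCI, 180 in LL2, 105 in MC38, 146 in B16F0 ATCC, 75 in B16F0 ECACC and 66 in TC1. Node 1 gave 62 in B16F10 ATCC and 32 in TC1, node 2 gave 65 in B16F10 ATCC and 47 in B16F0 ECACC, and node 4 gave 194 in LL2. C57BL/6J female spleen 2 gave 59 for spleens of all models, 151 in B16F10 ATCC, 38 in B16F10 NCI, 227 in MC38, 33 in B16F0 ATCC and 11 in B16F0 ECACC. Spleen 1 gave 3 in B16F10 ATCC, 6 in B16F10 NCI, 176 in LL2, 41 in MC38, 1 in B16F0 ATCC and 148 in PAN02. Spleen 3 gave 1 in B16F10 ATCC, 8 in B16F10 NCI, 156 in LL2, 46 in MC38, 0 in B16F0 ATCC and 158 in PAN02. Spleen 4 gave 30 in B16F10 ATCC, 56 in B16F10 NCI and 6 in B16F0 ECACC, and spleen 5 gave 1 in B16F0 ECACC. BALB/c nodes 6, 7, 8 and 10 gave 18, 20, 17 and 15 in 4T1. BALB/c spleen 6 gave 35 in CT26 and 55 in Renca, 7 gave 151 in 4T1 and 60 in CT26, 8 gave 13 in CT26 and 12 in Renca, 9 gave 55 in 4T1 and 83 in Renca, and 10 gave 16 in Renca. DBA/2J node 5 gave 71 in P815. Male nodes 1, 2, 4 and 5 gave 0 in TRAMPC2, male spleen 1 gave 0 in TRAMPC1, and male spleens 3, 4 and 5 gave 0 in TRAMPC1 and TRAMPC2.

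Among tumour-bearing mice, 4T1 nodes 34 and 36 gave 91 and 12, and 4T1 spleens 34 and 35 gave 53 and 131. CT26 nodes 25, 26, 27, 28 and 29 gave 577, 595, 569, 126 and 166, and CT26 spleens 26 and 27 gave 48 and 12. Renca nodes 21, 23 and 24 gave 731, 1665 and 666. B16F0 ATCC nodes 9, 10 and 12 gave 38, 33 and 36, and its spleens 7, 9 and 12 gave 29, 5 and 0. B16F0 ECACC nodes 1, 3, 4 and 6 gave 10, 79, 16 and 19, and its spleens 1 and 3 gave 2 and 1. B16F10 ATCC nodes 8 and 11 gave 25 and 26, and its spleens 8 and 12 gave 18 and 12. B16F10 NCI node 1 gave 15, and its spleens 1, 2, 3, 5 and 6 gave 9, 15, 64, 41 and 40. EL4 node 14 gave 185, LL2 node 16 gave 61, LL2 spleen 18 gave 85, and PAN02 spleens 1 and 6 gave 136 and 161. TRAMPC1 spleens 25, 26, 28 and 29, TRAMPC2 nodes 32, 33, 34 and 35 and TRAMPC2 spleens 31 and 34 gave 0. B16F10 NCI tumours 1, 5 and 6 gave 35, 11 and 11 against ATCC, tumour 6 gave 5 for B16F10 against B16F0, and TRAMPC2 tumour 33 gave 2. For the 23 counts of 0 by limma among these, 253 to 1209 genes had an unadjusted p under 0.05.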

Other observations

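The splits of the samples in this part were tests chosen after the results were seen, while the tests of Csf3, Csf2 and Csf1 were written down before theirs.

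The hypothesis that tumours with more transcripts of myeloid growth factors come with more neutrophil granule transcripts in the spleen was tested over 11 families, with 1e+05 permutations. For Csf3 Spearman rho was 0.182 (permutation p = 0.594, adjusted p = 0.924) and Pearson r 0.446 (permutation p = 0.171), with r = 0.0238 without 4T1 and CT26, the families farthest from the median Csf3 level. Within C57BL/6J females r was 0.258 and rho 0.257. For Csf2 rho was 0.0455 (permutation p = 0.905, adjusted p = 0.924) and r -0.109 (0.646 without Renca and EL4), and within C57BL/6J females r was -0.176. For Csf1 rho was -0.0364 (permutation p = 0.924, adjusted p = 0.924) and r -0.117 (0.216 without B16 and EL4), and within C57BL/6J females r was -0.182. Csf3 lay below 4.3, the level used as the expression minimum, in 10 of 11 families (4T1 at 4.81) and Csf2 in 10 of 11 (Renca at 4.63), so their correlations mostly rank background values and show nothing about these factors. Csf1 lay above it in all 11 and did not pass.

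Of 100 splits of the same samples, the real one included, the number calling at least as many genes was 1 for tumour against culture (real 1846, highest other 948), 1 for tumours among models (7252, 17), 3 for B16F10 against B16F0 (8, 18), 2 for B16F10 NCI against ATCC (17, 19), 1 for B16F0 ECACC against ATCC (65, 21) and 1 for CT26 against MC38 (778, 329). It was 1 for nodes overall (61, 14), spleens overall (31, 18) and the difference between organs (67, 25). Such low numbers, not adjusted over tests, argue against chance. For B16F10 against B16F0 the splits regroup mice and not the 2 stocks of each subline, so differences between stocks are not excluded there. For TRAMPC2 against TRAMPC1 (0, 79) all 100 did, as they must with a real 0.

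In nodes the number of the 100 splits was 1 for 4T1 (real 32, highest other 28), 1 for CT26 (340, 258), 1 for Renca (1097, 994), 1 for P815 (288, 222), 1 for B16F0 ATCC (68, 39), 2 for B16F10 ATCC (40, 40), 2 for B16F10 NCI (29, 29), 1 for LL2 (101, 35), 1 for MC38 (54, 48), 1 for EL4 (297, 210), 1 for TC1 (21, 10) and 1 for TRAMPC2 (1, 0). This argues against chance, but not for B16F0 ECACC, with 11 (31, 169). TRAMPC1 (0, 0) cannot be tested. Spleens gave 1 for B16F10 ATCC (52, 14), LL2 (267, 261), MC38 (148, 6), EL4 (498, 330), TC1 (277, 169) and TRAMPC2 (1, 0). They gave 2 for 4T1 (84, 118), PAN02 (254, 288) and TRAMPC1 (1, 1). They gave 3 for CT26 (23, 39), Renca (29, 63) and B16F10 NCI (25, 63). This argues against chance except for B16F0 ATCC, with 6 (8, 48), and P815, with 5 (1, 102). B16F0 ECACC (0, 17) is untestable. Splits called well over the real count in B16F0 ECACC nodes (169), in spleens of B16F0 ATCC (48), B16F0 ECACC (17), P815 (102), B16F10 NCI (63) and Renca (63), for TRAMPC2 against TRAMPC1 (79) and for B16F10 against B16F0 (18). They point to a structure of the samples, whose source was not tested.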
